A study of Rattus norvegicus with 9 samples.

How the data were processed

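The data were genomic DNA libraries made for methylation profiling from granulosa cells of 9 pools of third-generation rats, 3 pools each of the Control, DDT and Vinclozolin lineages. The method by which methylated DNA was captured is not given in the sources used here. Per the submitters' processing notes, the reads were handled with FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR on the rat build Rnor_6.0, and the versions, the order of steps and the counting options are not given there. The column names per the file headers are those the MEDIPS package writes.

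The authors deposited 2 tables, each setting the 3 libraries of a lineage beside the 3 Control libraries over the same 27820300 windows of 100 bp on 20 autosomes, X, Y and the mitochondrial genome. Per the file headers, the columns used hold the count of reads per window for each library. The Control counts were identical in both tables. The counts of Control 1 summed to 1.5 times the 77.7 M reads that its deposited RPKM values imply, as they would if a read counted in each window it overlapped, and neighbouring windows were treated as not independent. The highest count in any window was 300, reached in 44 windows, so the authors' counts appear capped there. RPKM columns of the deposited tables other than that one (11 columns) were not used. The authors' log2 fold change and p-value per window are present only where the 6 counts of a table sum to at least 40. Among windows whose deposited log2 fold change exceeded 1 in size, 100% had the sign of Control over lineage (146149 windows for DDT and 111297 for Vinclozolin), so signs were turned here to read lineage over Control.

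Counts of windows were summed to bins of 1 kb. Bins on autosomes and the X chromosome with a mean of at least 10 counts per library were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalisation, the quasi-likelihood fit and test with the dispersion trend estimated on every 20th bin, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Standard errors are the log2 fold change divided by the square root of its F statistic. Normalised counts are given as CPM, counts scaled by the library total after TMM. Called bins of the same direction within 1000 bp were merged to regions. Each lineage was fitted with the Controls on its own 6 libraries, and the lineages were compared with each other in a fit of all 9. Labels place each pool in its group, and all 9 libraries were used. Y and mitochondrial windows were left out of the tests.

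The groups, the bins, the filter, the normalisation, the tests and their thresholds were fixed before the data were examined. The subset of bins for the dispersion trend and the definition of clusters were chosen afterwards. So was the rule for named regions: without an annotation of the build, the first 5 regions per direction of each lineage against Control by the smallest p of their bins, given by position. For the direct comparison, 2 regions per direction were added after the values were seen. Tests of promoters, of gene lists and of CpG density were planned and not run, because no sequence or annotation of Rnor_6.0 was used here.

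Totals of 88.4 to 130.9 M counts per library set the precision. In data simulated for every 10th bin (211875 for DDT and 215202 for Vinclozolin, with the adjustment over these alone) and without change except in 200 bins, the test recovered 81.8% of bins changed by 4-fold, 29.9% of those changed by 2-fold and 1.5% of those changed by 1.5-fold in the DDT setting, and 72.7%, 22.4% and 1.5% in the Vinclozolin setting, with 3 and 5 false calls. Changes of 1.5-fold were thus rarely detectable in this simulation, and recovery with an adjustment over all bins was not simulated. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group, and a ratio with 1 to 3 counts carries an exact 95% binomial interval.

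Sharing between the lineages was compared with 3 simulations of unchanged groups against shared Controls. All 9 libraries, the Controls included, were simulated from 1 mean per bin. Clustering was compared with 1000 draws of tested bins matched on signal. Library-level shares were tested with exact permutation tests, for which 3 against 3 allows no p under 0.1. Alternatives were size factors by RLE, library totals, 1 factor per library in each of 100 strata of signal (chosen after seeing the data, in place of the correction for CpG density), other filters, bins of 500 bp, an adjusted p of 0.1, all 9 libraries in 1 fit, a term for the replicate number, each library left out in turn, and DESeq2 1.42.0 on every 10th bin. Windows of the authors' deposited table were counted at a p under 1e-05 and merged within 1000 bp. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.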

Results

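Granulosa cells are the somatic cells that surround the oocyte in the ovarian follicle, and they make estradiol under the drive of follicle-stimulating hormone. Methylation along their genomic DNA was profiled by sequencing in third-generation female rats of an outbred Sprague Dawley stock. The ancestral females had been injected during gestation days 8 to 14 with DDT (25 mg/kg body weight per day), with vinclozolin (100 mg/kg body weight per day) or with the DMSO vehicle alone. DDT is an organochlorine insecticide, and vinclozolin is a fungicide whose metabolites block the androgen receptor. Neither the first generation of offspring nor the generations after it were injected. The first generation was, however, in the womb during the injections. The title of the series sets the work in the context of ovarian pathology, polycystic ovaries and primary ovarian insufficiency. Females aged 20 to 22 days received 10 IU of a gonadotropin that stimulates follicle growth, and their granulosa cells were collected 2 days later.

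Each of the 9 libraries came from a pool of 4 to 9 rats, and the 3 pools of a group held different animals. Control libraries held 116.5, 130.9 and 106.4 M counts over windows of 100 bp. The DDT libraries were thinner, with 94.3, 88.4 and 88.7 M counts, and the Vinclozolin libraries held 108.1, 108.4 and 104.6 M. Across bins of 1 kb, the correlation between libraries was 0.860 to 0.906 within groups and 0.840 to 0.901 between groups. Control 3 correlated with Control 1 at 0.866 and with Control 2 at 0.873, less than any Vinclozolin library did with those Controls (0.888 to 0.901). Each library was counted as a replicate because the labels give different animals for each pool. Pools of a lineage can still share ancestral females, which the sample values used here do not number. The p-values by bin thus rest on the spread among pools within a lineage. They cannot separate the exposure from family differences between the lineages. Pairs of libraries of a group had a chi-square per degree of freedom of 2.27 to 3.06, and reads counted in more than 1 window would by themselves raise it above 1. Levels are given as CPM, counts scaled by the library's TMM-adjusted total. Read density per bin served as the measure of methylation, and it also follows CpG content, DNA copy number and mappability of the bin. Positions are on Rnor_6.0, and no gene annotation of that build was used here, so regions are given by position. Intervals and floors cover counting error only and treat counts as independent. In Control 1 a read gave 1.5 counts on average, so intervals are too narrow, and a floor of 3 reads in place of 3 counts would lower each bound about 1.5 times.

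The first comparison asked which regions differed between DDT-lineage and Control granulosa cells. On chromosome 3, the bin from 49554001 to 49555000 held no counts in any Control library and 67, 58 and 49 counts in the DDT libraries, at least 77-fold higher against a floor of 3 counts over the group (adjusted p = 1.23e-10). A bin on chromosome 2, 238522001 to 238523000, also held 0 counts in the Controls and 49, 17 and 60 counts in the DDT libraries, at least 55.8-fold higher (adjusted p = 3.36e-07). Normalised counts rose from 0.613 ± 0.169 to 2.18 ± 0.454 CPM (mean ± SD, n = 3 pools each) in the best bin of a region on chromosome 8 from 52244001 to 52247000 (log2 fold change 1.82 ± 0.2 SE, adjusted p = 1.9e-06 by edgeR). A bin on chromosome 1, 278450001 to 278451000, rose from 1.17 ± 0.116 to 3.27 ± 0.604 CPM (log2 fold change 1.47 ± 0.171 SE). Elsewhere on chromosome 1, 179689001 to 179690000 rose from 0.446 ± 0.010 to 1.45 ± 0.191 CPM (log2 fold change 1.70 ± 0.209 SE).

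Among the regions that were lower in the DDT lineage, the bin on chromosome 2 from 246891001 to 246892000 fell from 0.960 ± 0.263 to 0.230 ± 0.098 CPM (log2 fold change -2.06 ± 0.281 SE, adjusted p = 0.000301 by edgeR). A pair of bins lay about a megabase apart on chromosome 15. The one at 39685001 to 39686000 held 119 counts over the Controls and 6 over the DDT libraries (log2 fold change -3.85 ± 0.572 SE, or -4.56 with 500-bp bins). The one at 38646001 to 38647000 held 166 and 15 counts (log2 fold change -3.07 ± 0.465 SE). That call was lost without Control 3 (adjusted p = 0.0562) or without DDT 1 (adjusted p = 0.0606), and its log2 fold change was -4.04 without DDT 2. On chromosome 1, 21676001 to 21677000 fell from 1.28 ± 0.483 to 0.412 ± 0.186 CPM. Its call was lost without Control 1 (adjusted p = 0.196), DDT 1 (0.108) or DDT 3 (0.0582). A bin on chromosome 11, 17228001 to 17229000, fell from 1.31 ± 0.184 to 0.502 ± 0.160 CPM, and it missed the threshold only with 500-bp bins (adjusted p = 0.0788).

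In total, 313 of 2118743 tested bins passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 243 higher (77.6%) and 70 lower in the DDT lineage. They merged into 291 regions, 225 higher with a median log2 fold change of 1.19 and 66 lower with a median of -1.55. Most of them (270) were a single bin, and 21 lay on the X chromosome, 17 higher and 4 lower in DDT. The bins higher in DDT made up 67.7% of 303 calls after scaling within strata of signal, and 63.5% of 554 calls among bins with a mean of at least 50 counts. The count rested on single libraries: it was 45 without Control 1, 78 without Control 2, 44 without DDT 1, 56 without DDT 3 and 1088 without DDT 2. It was 506 with no filter on low counts, 945 with all 9 libraries in the fit and 113 with 500-bp bins.

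**Figure D1:**
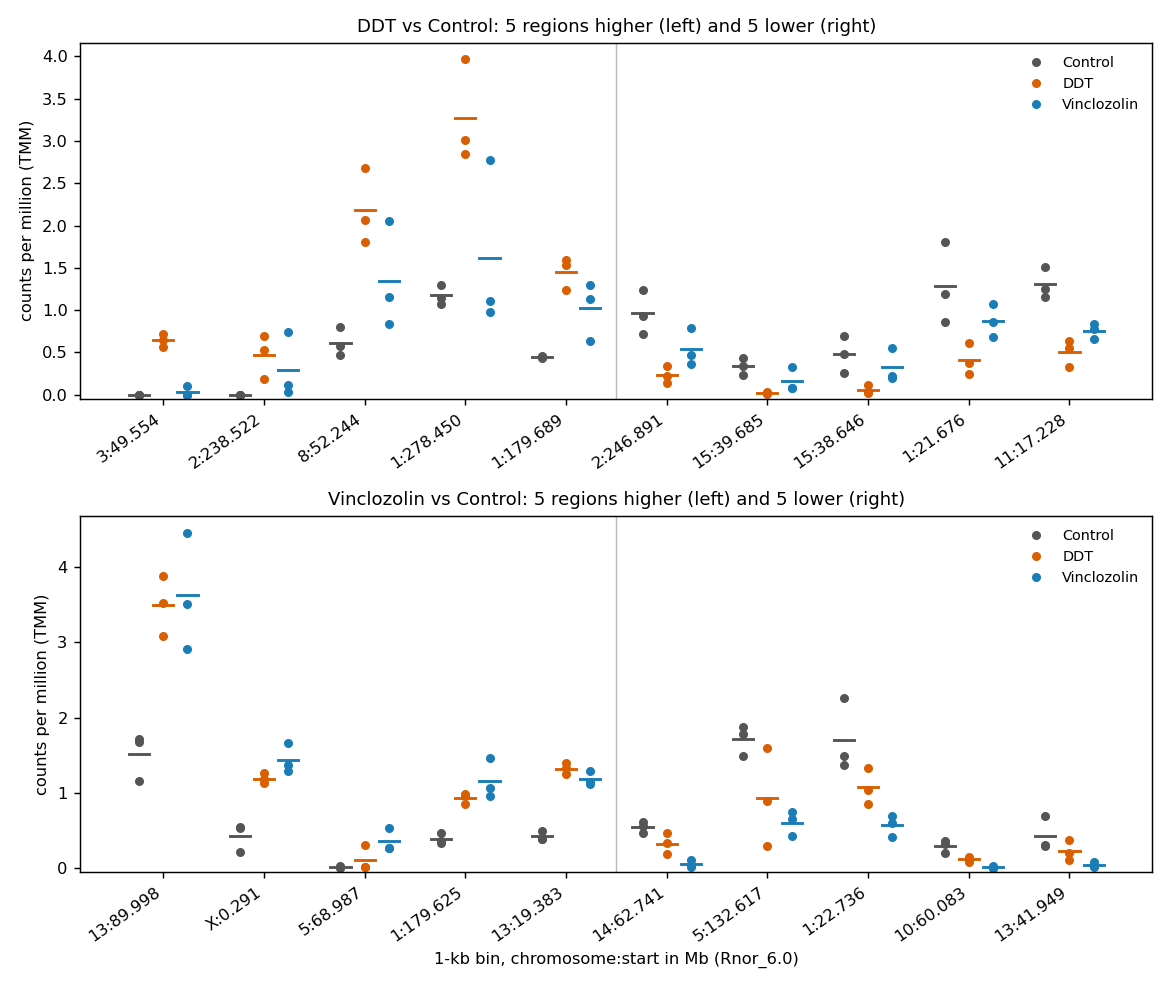
Normalised counts per library (CPM, linear axis) in the best bin of each named region of DDT against Control (top) and Vinclozolin against Control (bottom), with 5 regions higher in the lineage on the left and 5 lower on the right. Points are the 3 pools of each group and short bars their means, and the Controls of the chromosome 3 bin at 49554001 sit at 0.

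The Vinclozolin lineage was compared with the same 3 Control libraries. Among the regions lower in the Vinclozolin lineage, on chromosome 14, 62741001 to 62742000 fell from 0.545 ± 0.075 to 0.057 ± 0.050 CPM (log2 fold change -3.24 ± 0.403 SE, adjusted p = 4.21e-05 by edgeR, and -4.21 without Vinclozolin 1). A region on chromosome 5, 132617001 to 132619000, fell in its best bin from 1.72 ± 0.203 to 0.606 ± 0.163 CPM (log2 fold change -1.51 ± 0.188 SE). A bin on chromosome 1, 22736001 to 22737000, fell from 1.71 ± 0.479 to 0.573 ± 0.144 CPM (log2 fold change -1.58 ± 0.198 SE). On chromosome 10, 60083001 to 60084000 held 107 counts over the Controls and 3 over the Vinclozolin libraries, all 3 of them in Vinclozolin 2, a ratio of 31.4 with an exact 95% counting interval of 10.5 to 154.8. On chromosome 13, 41949001 to 41950000 held 154 counts over the Controls and 14 over the Vinclozolin libraries (log2 fold change -3.26 ± 0.466 SE, and -4.15 without Vinclozolin 3). Its call was lost without Control 1 (adjusted p = 0.0999) and with 500-bp bins (log2 fold change -2.61, adjusted p = 0.0612).

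Regions higher in the Vinclozolin lineage included a bin on chromosome 13, 89998001 to 89999000, which rose from 1.52 ± 0.312 to 3.63 ± 0.779 CPM (log2 fold change 1.25 ± 0.155 SE, adjusted p = 4.21e-05 by edgeR). Near the start of the X chromosome, the region from 291001 to 293000 rose in its best bin from 0.432 ± 0.185 to 1.44 ± 0.198 CPM (log2 fold change 1.71 ± 0.215 SE). A bin on chromosome 5, 68987001 to 68988000, held 4, 0 and 1 counts in the Controls and 28, 29 and 55 in the Vinclozolin libraries (log2 fold change 4.55 ± 0.603 SE). That value was 6.07 without Control 1 and 3.94 without Control 2. On chromosome 1, 179625001 to 179626000 rose from 0.388 ± 0.068 to 1.16 ± 0.269 CPM. A second bin on chromosome 13, 19383001 to 19384000, rose from 0.424 ± 0.061 to 1.19 ± 0.096 CPM.

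Across 2152020 tested bins, 221 passed edgeR's quasi-likelihood test at an adjusted p of 0.05 (Benjamini-Hochberg), 153 higher (69.2%) and 68 lower in the Vinclozolin lineage. They merged into 198 regions, 135 higher with a median log2 fold change of 1.43 and 63 lower with a median of -1.72. Of these, 33 lay on chromosome 1, 21 on chromosome 7 and 14 on the X chromosome. Scaling within strata of signal gave 213 calls, 55.9% of them higher in Vinclozolin, and a mean of at least 50 counts gave 202 calls, 56.4% of them higher. Without single libraries the count was 118 (Control 1), 92 (Control 2), 342 (Vinclozolin 1), 49 (Vinclozolin 2) and 42 (Vinclozolin 3), and bins higher in Vinclozolin were 46.9% of the calls without Vinclozolin 2 and 45.2% without Vinclozolin 3. It was 145 with 500-bp bins.

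Both lineages shared part of their changed bins. Of 2090317 bins tested in both comparisons, 38 passed in both, 35 higher in both lineages, 3 lower in both and 0 in opposite directions. The 35 bins had a median log2 fold change of 1.44 in the DDT and 1.45 in the Vinclozolin lineage, and the 38 bins lay on 15 chromosomes. They included the chromosome 2 bin at 238522001, where the Vinclozolin libraries held 78, 12 and 3 counts, most of them in Vinclozolin 1 (at least 35.2-fold above the Controls, adjusted p = 0.001 by edgeR). The chromosome 13 bin at 89998001 was among them (log2 fold change 1.20 in DDT, adjusted p = 0.000544), as were the X bin at 291001 (1.44 in DDT, adjusted p = 0.00538) and the chromosome 13 bin at 19383001 (1.63 in DDT, adjusted p = 0.000146). On chromosome 1, the bins at 179625001 (1.25 in DDT, adjusted p = 0.0292) and 179689001 (1.18 in Vinclozolin, adjusted p = 0.0303) passed in both as well.

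Because both comparisons used the same 3 Controls, some sharing arises without any change in the lineages. Independent lists of these sizes would share 0.0155 bins higher in both and 0.00228 lower in both. For the simulated unchanged groups all 9 libraries were drawn, the Controls included, so traits of the real Control libraries did not enter. Set against the same simulated Controls, these groups had 0 called bins in either comparison in all 3 draws. They therefore give no expectation for called bins in both. At an unadjusted p under 0.001 in both and the same direction, they held 75.3 bins on average, against 671 in the data. The simulated libraries shared 1 mean per bin and so had no trend of the fold change with signal. Both lineages had such a trend against the Controls, with medians of -0.17 (DDT) and -0.18 (Vinclozolin) in the lowest decile of signal. The simulation is therefore not a full expectation for unchanged groups. The covariance of the fold changes across bins was 0.0733, against 0.0618 in the simulated groups, and their correlation was 0.447 against 0.482. With 3 Controls, separate sets of Controls could not be put against each lineage. The part of the excess that rests on the Controls themselves was thus not separated, nor was the part that rests on the trend with signal. The 38 shared bins became 14 without Control 1, 19 without Control 2, 14 without DDT 1, 14 without DDT 3, 17 without Vinclozolin 2 and 13 without Vinclozolin 3.

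Part of the called regions lay in clusters. By a definition chosen after seeing the data, clusters of at least 4 regions of a comparison, each within 500 kb of the next, numbered 5 in the DDT comparison with 26 of its 291 regions (8.9%) and 12 in the Vinclozolin comparison with 78 of its 198 regions (39.4%). The union held 13 clusters, 10 higher and 3 lower in the lineages. A cluster on chromosome 1, 179104001 to 179698000, held 59.1 ± 4.20 CPM in the Controls, 76.4 ± 1.98 in DDT and 83.8 ± 20.5 in Vinclozolin (n = 3 pools each). The cluster on chromosome 8, 10349001 to 10713000, held 22.5 ± 3.02, 34.96 ± 2.06 and 40.1 ± 9.66 in the same order, and the cluster at the start of the X chromosome, 114001 to 324000, held 14.7 ± 2.98, 25.3 ± 0.550 and 29.3 ± 8.84. In the lower direction, the cluster on chromosome 16 from 64931001 to 64957000 held 35.1 ± 3.29 in the Controls, 21.4 ± 3.27 in DDT and 23.5 ± 10.2 in Vinclozolin. Vinclozolin 1 lay least far of its group in the direction of the cluster in 11 of the 13 clusters. It held 60.4 CPM in the chromosome 1 cluster, against 97.7 and 93.4 in the other Vinclozolin libraries and 54.2 to 62.0 in the Controls. Vinclozolin 1 thus lay inside the Control range there. The same held for the clusters starting at 32749001 on chromosome 4, 21165001 on chromosome 7, 65154001 on chromosome 15 and 150241001 on X. In the remaining clusters it lay beyond all Controls in the cluster's direction. Control 3 was lowest of the Controls in the direction of the cluster in 10 of the 13, which enlarged the difference between lineage and Control there. In the lower clusters of chromosomes 1 and 5, Control 3 also had the lowest CPM of the Controls (277.8 and 139.5), which reduced the difference. The number of DDT clusters was 0 without Control 1, 1 without Control 2, 6 without Control 3, 1 without DDT 1, 20 without DDT 2 and 0 without DDT 3. That of Vinclozolin clusters was 7 without Control 1, 3 without Control 2, 7 without Control 3, 15 without Vinclozolin 1 (with 180 of 285 regions), 1 without Vinclozolin 2 and 1 without Vinclozolin 3. These fits held 42 to 1026 DDT regions and 42 to 285 Vinclozolin regions, and fewer regions give fewer clusters by construction. A loss of clustering was thus not separated from a loss of calls.

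**Figure D2:**
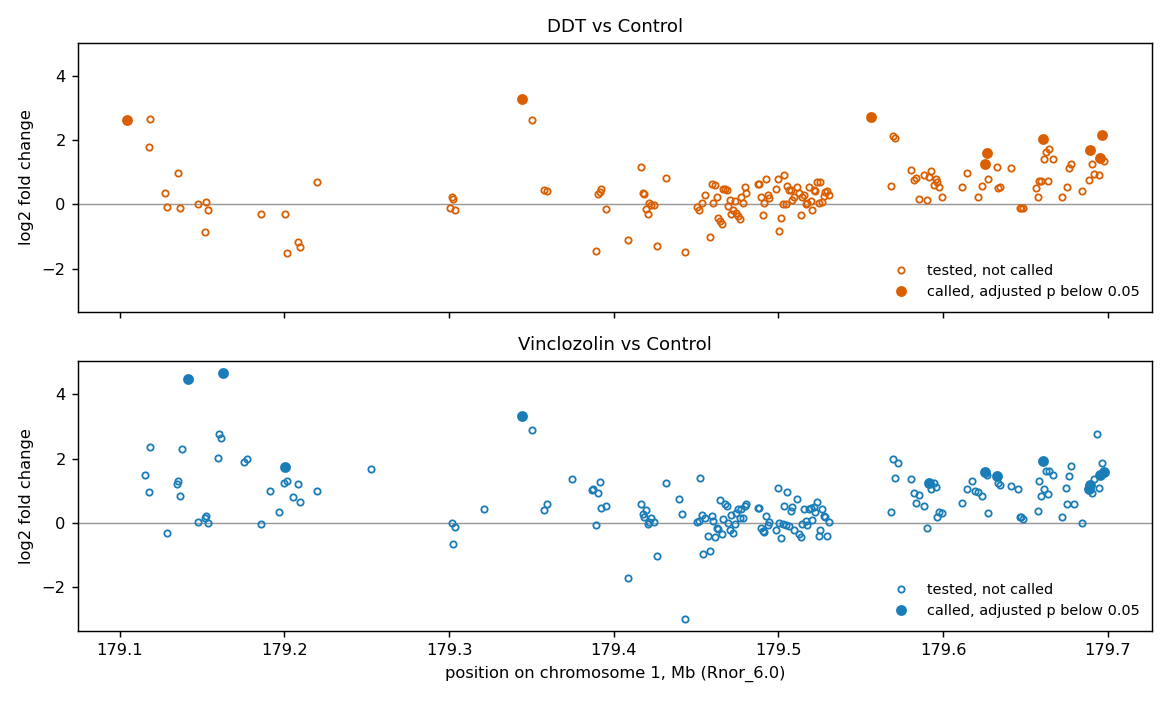
Log2 fold change of each tested 1-kb bin along the cluster on chromosome 1 from 179104001 to 179698000 (position in Mb), for DDT against Control and Vinclozolin against Control. Filled points are called bins (all above 0) and open points are bins tested but not called.

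**Figure D3:**
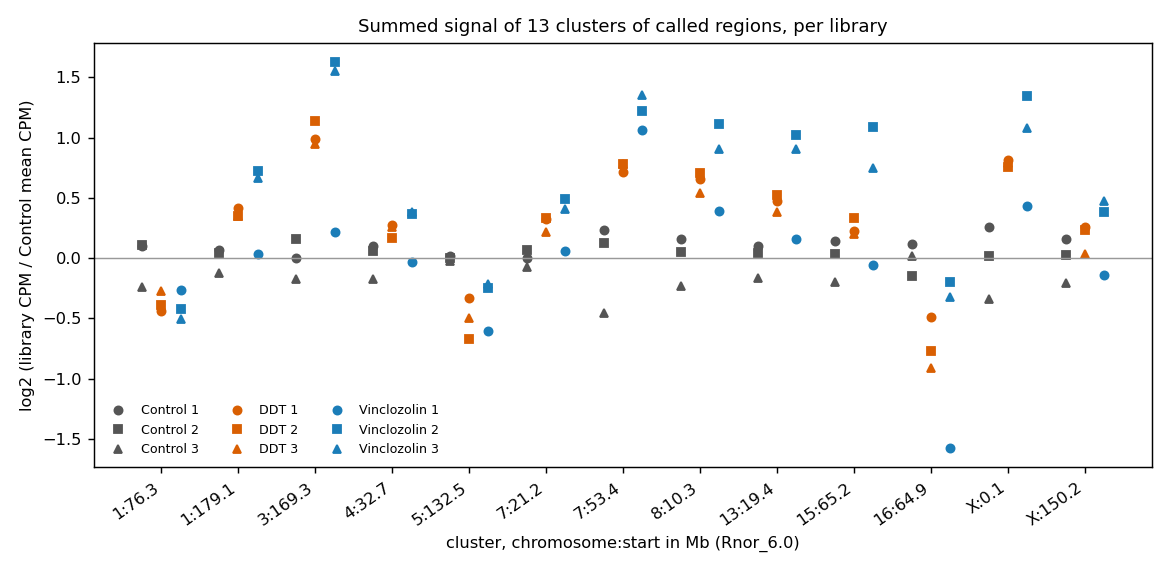
Summed CPM of each library in each of the 13 clusters, as log2 relative to the mean of the Controls. Marker shapes give the 3 pools of each group. Vinclozolin 1 (blue circles) lay least far of its group in the direction of the cluster in 11 of the 13 clusters, in some of them inside the Control range.

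The lineages were also compared directly, in a fit of all 9 libraries. The regions named here were chosen after their values were seen. The smallest p belonged to a bin on chromosome 1, 159567001 to 159568000, with 2.76 ± 0.371 CPM in Vinclozolin, 1.49 ± 0.436 in Control and 0.783 ± 0.091 in DDT (n = 3 pools each). Its log2 fold change of Vinclozolin over DDT was 1.81 ± 0.182 SE (adjusted p = 6.01e-08 by edgeR). A bin on chromosome 9, 121674001 to 121675000, held 1.58 ± 0.233 CPM in Vinclozolin, 0.814 ± 0.258 in Control and 0.414 ± 0.021 in DDT. On chromosome 11, the region from 82208001 to 82212000 went the other way, with 0.094 ± 0.107 CPM in Vinclozolin, 0.285 ± 0.116 in Control and 0.777 ± 0.070 in DDT in its best bin (log2 fold change -3.02 ± 0.399 SE, and -4.49 without Vinclozolin 2). The chromosome 3 bin at 49554001 held 174 counts over the DDT libraries and 10 over the Vinclozolin libraries, all 10 in Vinclozolin 3 (log2 fold change -4.29 ± 0.554 SE, adjusted p = 3.54e-05). Without that library the fit gave -9.08 against 0 counts, which is no bound.

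By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1088 of 2108798 bins differed between the lineages, 795 higher in Vinclozolin (73.1%) and 293 higher in DDT. They merged into 1058 regions with median log2 fold changes of 1.09 and -1.21. On the X chromosome lay 83 of them (7.8%, against 4.7% of the tested bins, two-sided Fisher's exact test, p = 1.24e-05, adjusted p = 0.000261 over chromosomes), 78 higher in Vinclozolin. Neighbouring bins are not independent, so this p is too small by an unknown amount. Called bins on the X chromosome numbered 84, and without single libraries 10 (DDT 1), 212 (DDT 2), 20 (DDT 3), 34 (Vinclozolin 1), 14 (Vinclozolin 2) and 8 (Vinclozolin 3). The Fisher's exact p was 0.362 without DDT 1, 0.0763 without Vinclozolin 2 and 0.402 without Vinclozolin 3. Scaling within strata of signal gave 1692 calls in all, 56.5% of them higher in Vinclozolin, and the 6 libraries alone gave 1706. Leaving out a library gave 164 (DDT 1), 3294 (DDT 2), 226 (DDT 3), 449 (Vinclozolin 1), 181 (Vinclozolin 2) and 128 (Vinclozolin 3).

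The submitters' own test per window of 100 bp pointed to several of the same places. In the authors' deposited table for DDT, 1365 windows had a p under 1e-05 (45.6 would by chance), 1011 of them higher in DDT. Their smallest p in that direction, 2.23e-24 in the authors' deposited table, belonged to the window on chromosome 8 from 52246101 to 52246200, inside a region of 12 windows from 52243401 to 52246600. The smallest p among windows lower in DDT, 9.65e-11 in the authors' deposited table, fell on chromosome 5 at 56903801 to 56903900. For Vinclozolin, the authors' deposited table held 708 such windows (50 by chance), 404 of them higher in Vinclozolin. There, the smallest p values of the authors' deposited table were 6.65e-16 on chromosome 1 at 22736701 to 22736800, lower in Vinclozolin, and 5.9e-15 on chromosome 15 at 24651001 to 24651100, higher in Vinclozolin. Regions merged from the windows of the authors' deposited table overlapped 128 of the 291 DDT regions (44.0%) and 94 of the 198 Vinclozolin regions (47.5%) in the same direction. In reverse, 134 of the 1031 DDT regions of the authors' deposited table (13%) and 94 of the 584 for Vinclozolin (16.1%) met a region of the bin test.

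Library-wide shares were compared between groups, and none of the 18 tests passed. The tenth of bins with the most signal took 36.2 ± 1.47% of the counts in the Controls, 37.2 ± 1.23% in DDT and 38.5 ± 0.558% in Vinclozolin (mean ± SD, n = 3 pools each). All Vinclozolin libraries lay above all Controls (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.18 over 18 tests), while DDT and Control overlapped (exact permutation p = 0.5). With windows of 100 bp in place of bins, Vinclozolin and Control overlapped as well, at 46.50% in Vinclozolin 2 and 46.57% in Control 2. Across bins, the median log2 fold change rose with signal, from -0.17 in the lowest decile to 0.08 in the ninth for DDT, and from -0.18 in the lowest to 0.13 in the highest for Vinclozolin. The X chromosome took 4.64 ± 0.087% of counts in the Controls, 4.36 ± 0.102% in DDT and 4.60 ± 0.055% in Vinclozolin. All DDT libraries lay below all Controls in this share (two-sided exact permutation p = 0.1, adjusted p = 0.18), and Vinclozolin and Control overlapped (exact permutation p = 0.6).

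**Figure D4:**
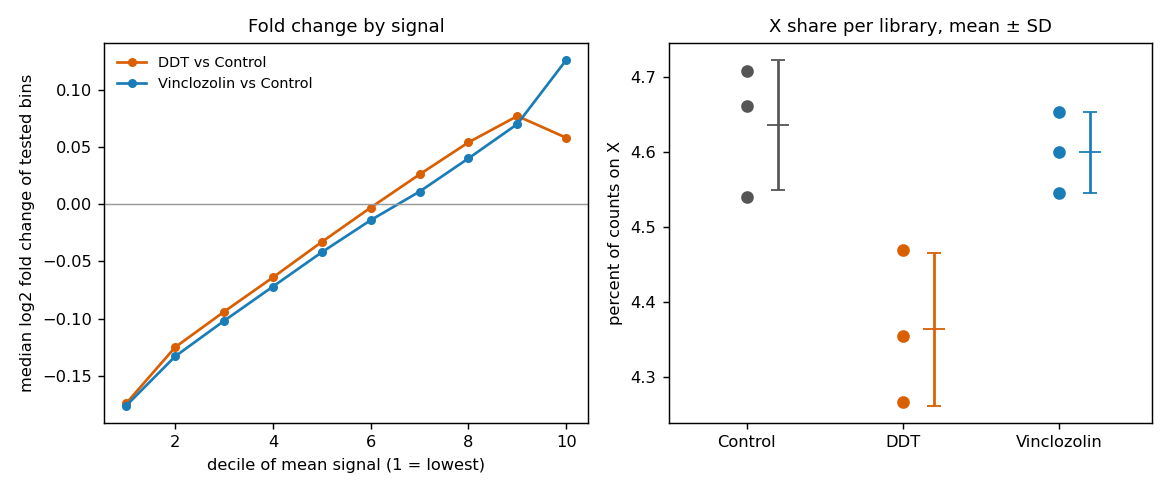
Median log2 fold change of tested bins by decile of mean signal for each lineage against Control (left), and percent of counts on the X chromosome per library with the group mean ± SD (right). The medians run from -0.17 in the lowest decile to 0.08 in the ninth for DDT, and the DDT libraries lie between 4.27% and 4.47% on the X chromosome, below the 3 Controls.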

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

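Tests of the trend with signal in the share of higher calls, of copy number or sequence and of a shared property of the libraries, and the values of blocks of 100 kb in strata of signal and of clusters without single libraries, were chosen only after the results they bear on were seen.

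For 4 of the regions named against Control, the lineages differed from each other in the direct test. The chromosome 3 bin at 49554001, higher in DDT than in Control, had a log2 fold change of Vinclozolin over DDT of -4.29 (adjusted p = 3.54e-05 by edgeR). All 10 Vinclozolin counts there were in Vinclozolin 3, and the fit without it gave -9.08 against 0 counts, which is no bound. For the chromosome 1 bin at 278450001, also higher in DDT, it was -1.01 (adjusted p = 0.02). The chromosome 15 bin at 38646001, lower in DDT, gave 2.51 (adjusted p = 0.0207), and its call against Control was lost without Control 3 (adjusted p = 0.0562) or DDT 1 (0.0606). The chromosome 14 bin at 62741001, lower in Vinclozolin, gave -2.51 (adjusted p = 0.00579).

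More called bins were higher than lower in both lineages, and fold changes also rose with signal. If that trend alone made the excess, scaling within strata of signal should bring the higher share near 50%. For DDT the share went from 77.6% to 67.7% (exact 95% interval 62.1 to 72.9), an interval above 50%. For Vinclozolin it went from 69.2% to 55.9% (exact 95% interval 48.9 to 62.6), an interval that holds 50%. Scaling thus took away part of the excess in both lineages. The intervals treat called bins as independent, which they are not, and do not measure the spread between pools. They therefore cannot decide whether the trend is the whole cause in either lineage. Whether the trend itself reflects capture efficiency or methylation of signal-rich DNA stays open, and a difference between the lineages remains an untested explanation.

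Called regions lay closer together than matched draws. In the DDT comparison 28.2% of regions lay within 500 kb of another, and in the Vinclozolin comparison 53.0%. In 1000 draws of bins matched on signal the shares were at most 16.8% and 15.2%, which argues against signal-rich stretches as the source. Without Vinclozolin 1, 2 and 3 in turn, the Vinclozolin share was 68.8% of 285 regions, 34.1% of 44 and 31% of 42. With fewer regions the share falls by construction, and draws were made only with all libraries. Uncalled bins in the clusters moved the same way, with a median log2 fold change in the cluster's direction of 0.48 for DDT and 0.56 for Vinclozolin, against 1.49 and 1.51 in called bins, which were selected for size. Thus DNA that differs in copy number or sequence between pools of outbred rats and a broad methylation change cannot be told apart, because read density follows both. The libraries deviated together across clusters on different chromosomes with a mean correlation of 0.306 (median 0.102 in 1000 matched sets, 48 of which were as high), so a shared property of the libraries cannot be told apart from chance by these 9 libraries. An effect of ancestral exposure on whole neighbourhoods stays among the open explanations.

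The X chromosome took a lower share of counts in the DDT libraries. Within strata of signal, the lowest Control still lay above the highest DDT library by 0.014 on the log2 scale, which is less than the larger group range of 0.059, so the trend with signal on X and a shift of X itself cannot be told apart with 3 pools each. DDT minus Control was -0.081 in the upper and -0.073 in the lower part of the signal range, and the values of the DDT libraries overlapped between them. In blocks of 100 kb, the median log2 fold change on X was -0.101 under TMM and -0.046 in strata of signal, with 84 of 100 and 2 of 7 called X blocks lower in DDT, against 511 of 1329 and 15 of 66 over all called blocks. Like values in both parts of the signal range are what a shift of X bins alike would give, as from a change in X methylation or X dose. Of the 21 called X regions of 1-kb bins, 17 were higher and 4 lower in DDT, opposite to the lower X share. Over all chromosomes 225 of 291 regions were higher in DDT, so the X regions followed the general excess of higher calls. In the direct comparison 78 of the 83 X regions were lower in DDT than in Vinclozolin, against 783 of 1058 over all chromosomes. The number of X calls in that comparison rested on single libraries. Called regions thus do not decide for or against a shift of X. No test here separates X methylation from X dose.

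Splitting the 6 libraries of a comparison into 3 and 3 in all 10 ways is too few for a share under 0.05. The real split gave the most calls, 1 of 10 splits in each comparison: 313 for DDT against Control (highest other 5), 221 for Vinclozolin against Control (highest other 26) and 1706 for Vinclozolin against DDT fitted on its 6 libraries (highest other 30).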

How the results depend on the processing

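Settings chosen only after the results were seen were the strata of signal, alone or with the replicate term, and the overlap without single libraries. None of the 24 fold changes of named regions changed sign in any setting run. These regions were chosen by the smallest p in the same data, so a change of sign was unlikely beforehand. Higher calls outnumbered lower ones in each count of bins below except for Vinclozolin without Vinclozolin 2 or without Vinclozolin 3. Called bins went to 1127 (DDT) and 414 (Vinclozolin) at an adjusted p of 0.1, by construction a looser threshold. With 500-bp bins they were 113 and 145, by construction thinner bins. For DDT they were 506 with no filter, 554 with a mean of 50 counts and 945 with all 9 libraries. For Vinclozolin against DDT they were 1692 in strata of signal and 1706 with 6 libraries. Leaving out single libraries gave 44 to 1088 (DDT), 42 to 342 (Vinclozolin), 128 to 3294 (Vinclozolin against DDT) and 13 to 54 shared bins. On every 10th bin DESeq2 called 236 against 37 by edgeR for DDT and 117 against 26 for Vinclozolin, with 21 and 5 called by both, but DESeq2 gave no adjusted p for 176634 of 211875 and 204442 of 215202 of these bins, so the lists are not like for like. Of the windows in the authors' deposited table, 4870 and 2954 had a p under 1e-04 and 438 and 208 a p under 1e-06, and at a p under 1e-05, 162 and 87 regions held at least 2 windows, fewer by construction. For the others the cause was not tested. The replicate numbers did not pair libraries (correlation of same-numbered deviations -0.024 to 0.051), and a replicate block gave 374, 193 and 1539 bins, or 721 (DDT) and 3030 (Vinclozolin against DDT) together with strata of signal. The other 36 values of the main results stayed within 1.5 times or 1 SD, and of the values of single regions and lesser results 352 kept their side, 12 moved and 8 fell short of the threshold. Alternatives fixed in advance and not run were those for promoters, gene lists and library CpG enrichment, the correction for CpG density with and without the replicate block, and the CpG density of called bins. At this depth the test recovered 29.9% (DDT) and 22.4% (Vinclozolin) of 2-fold changes simulated on a subset of every 10th bin.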

Other observations

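Tests of single libraries left out of the clusters, and the block counts in strata of signal, were chosen after the results were seen. A run of 5 bins on the X chromosome, 79462001 to 79467000, held 6 counts over the 3 Control libraries, 194 over the DDT libraries (34 to 94 per library) and 10 over the Vinclozolin libraries. Its first bin held 0 counts in the Controls and 66 in DDT, at least 29.2-fold higher (adjusted p = 0.000544 by edgeR), and its last held 0 and 65, at least 28.8-fold higher. Elsewhere on X, 145965001 to 145966000 held 0 counts in DDT and 65 in the Controls, at least 16.3-fold lower in DDT (adjusted p = 0.00532), with 18 counts in Vinclozolin. In all, 8 called DDT bins and 4 called Vinclozolin bins had at most 3 counts over a group. Among them, chromosome 17 at 57081001 to 57082000 held 2 counts in DDT and 64 in the Controls (ratio 24.1, exact 95% counting interval 6.4 to 203.3), and chromosome 1 at 179141001 to 179142000 held 3 counts in the Controls and 66 in Vinclozolin (6, 43 and 17 per library, ratio 25, interval 8.2 to 124.1), most of them in Vinclozolin 2.

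Of the 38 bins called in both lineages, 22 (57.9%) lay in the 13 clusters. Clusters were built from the calls of these same comparisons, so part of this share arises by construction. Of all called regions, 8.9% (DDT) and 39.4% (Vinclozolin) lay in clusters of their own comparison. On the X chromosome the clusters around 150241001 to 150620000 held 3 shared bins higher and 1 shared bin lower in both lineages. In the lower direction, the cluster on chromosome 1 from 76279001 to 77303000 held 327.1 ± 42.7 CPM in the Controls, 254.0 ± 15.0 in DDT and 248.7 ± 21.03 in Vinclozolin (mean ± SD, n = 3 pools each). The cluster on chromosome 7 from 53431001 to 53552000 held 7.24 ± 1.73, 12.3 ± 0.350 and 16.8 ± 1.65. With all libraries 53.0% of 198 Vinclozolin regions lay within 500 kb of another. The share was 68.8% of 285 regions without Vinclozolin 1, 34.1% of 44 without Vinclozolin 2 and 31% of 42 without Vinclozolin 3. With fewer regions this share falls by construction. In blocks of 100 kb, 1329 differed between DDT and Control by edgeR, 100 of them on X (84 lower), and in strata of signal 66 differed, 7 of them on X (2 lower). For Vinclozolin, 3 blocks differed from Control in either scaling. Neither lineage had all of its libraries above all Controls in the share of Y or mitochondrial counts.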
